A study of Mus musculus with 2 samples.

How the data were processed

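The samples form 1 group: H3K4me1 chromatin immunoprecipitation and sequencing of facial prominences from B6NCrl embryos at day 15.5, in 2 biological replicates from separate pools of 78 and 62 embryos, both sexes together, per the labels. The labels give a size range of 300 to 500 bp for both libraries. The files were 4 peak lists in narrowPeak form on mm10, per the sample text files that came with them. These say that replicate 1's list was derived from its alignments and 2 further files, replicate 2's from the alignments of its 2 technical replicates and 1 further file, the pooled list from both replicates' alignments and 2 further files, and the list of replicated peaks from the other 3 lists. The kind of the further files, the aligner, the peak caller, its settings and the rule for replicated peaks are not given in the sources used here. The input control named in the labels was not analysed here.

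Each line of the deposited lists gives a peak's start and end, a display score scaled by the authors within each list, its fold enrichment as a ratio over the authors' control or background, its −log10 p-value and −log10 q-value by the authors' caller, and the summit's offset. The authors' score and summit offset were not used. Neither fold enrichment nor −log10 values were compared between lists, because the deposited values were not normalized between them. The highest p-value of a deposited peak was 0.009996 in replicate 1 and 0.00938 in replicate 2, and q was at most 0.01 for 69.9% and 76.8% of their peaks. Depth is unknown, since the lists hold no read counts. The spread between the 2 replicates, given as SD with n = 2, is the main measure of precision. For ratios of words this SD can understate the error, and an SE over chromosomes is given as well.

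Coordinates were read against GRCm38.p6, the assembly named mm10 in the files, after its chromosome names and lengths were compared with the peaks. Genes, transcripts and exons came from GENCODE M21. Peaks on chromosomes 1 to 19, X and Y were used, and 1 to 4 peaks per list on unplaced scaffolds were left out. No peak of a list overlapped another of the same list.

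Replicate overlap counted peaks that share at least 1 base with a peak of the other replicate. Chance levels came from 100 circular shifts of 1 list within each chromosome, in coordinates without assembly gaps, and p-values are one-sided permutation values whose smallest possible value is 0.0099. Genomic location was taken at the middle of each peak, in the order within 1 kb of any start site, exon, intron and between genes, against 100 shifts of the peaks. The promoter profile was the percent of protein-coding start sites (the gene's annotated 5' end) covered at steps of 100 bp up to 5 kb; a marked flank means a replicated peak from 500 bp to 3 kb from the start site on either side. For each protein-coding gene the percent of bases within 50 kb of the start site in peaks was computed. The median over each of 15 gene lists (facial mesenchyme regulators, facial signalling, cartilage and bone, surface epithelium, tooth matrix, skeletal muscle, endothelium, blood and immune, crest glia and melanocyte, forebrain neuron, heart, liver, germ cell, Hox and housekeeping genes) was set against 10000 random lists of the same size, matched on the number of coding start sites in the window in 5 classes. All genes of the lists were found in the annotation. These percentiles describe the libraries and are no test, because genes are not replicates. Peaks within 3 kb of each other were joined into domains, ranked by bases in peaks.

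For binding-site words, 22 sequences were counted on both strands in replicated peaks over 1 kb from any start site. Each peak was paired with a window of the same width and chromosome, outside any pooled peak and within 2 percentage points of its GC content. Of 89432 such peaks, 2771 found no window and were left out. The ratio of hits per kb has a standard error from a jackknife over chromosomes and a 95% interval from it.

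Named genes followed a rule fixed before the data were examined, as were the lists and the words. They are the 20 protein-coding genes with the highest percent of the window in replicated peaks that are also in the top 5% by each replicate's own peaks, keeping 1 gene per 200 kb; in each list the 3 highest members and the lowest; and the gene nearest to each of the 15 domains with most bases in peaks.

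The overlap, location, gene list, density and spacing statistics were tested on simulated data. With 20.0% and 59.9% of 195123 peaks planted as shared, the overlap above chance came out at 19.8% and 59.8%. For 120755 peaks shifted at random within chromosomes, the folds over chance in the 4 places lay between 0.989 and 1.03. The chance level comes from the same kind of shift, so this checks the computation only. Of 200 random gene lists drawn from the 21938 genes, 4.5% lay above the 95th percentile, and of 200 lists whose members' percent was doubled with 2 added, 85.5% did. A planted density ratio of 1.50 in 20000 sequences of random bases came out at 1.52, and a pair of words planted at a spacing of 6 bases was recovered at 6. The pairing with windows matched on GC was not part of these simulations.

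Alternatives fixed beforehand were a q-value of at most 0.01, peaks above their list's median fold enrichment, other overlap rules, autosomes only, promoter windows of 2.5 kb, any overlap in place of the middle, protein-coding genes only, start sites over 10 kb from any other, gene windows of 20 and 100 kb, unmatched random lists, numbers of peaks, windows without the 2.5 kb around start sites, a shorter joining distance of 1 kb and a longer one, distal peaks only, shuffled words, windows not matched on GC, the middle 500 bases of peaks, and each replicate's own list alone. Chosen after seeing the data were random lists matched also on window GC, and lists without genes on X and Y. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0, and figures matplotlib 3.10.9.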

Results

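H3K4me1, the histone H3 lysine 4 monomethylation known from enhancers and from the flanks of active promoters, was mapped by chromatin immunoprecipitation and sequencing in the facial prominences of B6NCrl mouse embryos. The tissue, which holds neural-crest mesenchyme, surface epithelium and other cell types of the forming face, was taken at embryonic day 15.5 from pools of male and female embryos. The samples formed 1 group of 2 biological replicates, from pools of 78 embryos (replicate 1) and 62 embryos (replicate 2). No other tissue, age or antibody was compared, so the questions asked of the data were how far the replicates agreed, where in the genome the mark lay and at which genes. The files were the authors' peak lists on mm10, called on each replicate alone and on both together, with a further list of replicated peaks. Read counts were not part of these lists, so the depth of each library is unknown and no interval that needs it is given.

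In the replicated list the top fold enrichment, 9.62, belonged to a peak at chromosome 8, 120263903 to 120272017, inside Gse1. The next, 9.38, belonged to a peak at chromosome 1, 36579066 to 36582400, outside the nearest gene, Sema4c, which was named after the values were seen. The third-highest value, 9.26, belonged to a peak at chromosome 11, 120258683 to 120267136, inside Bahcc1. In replicate 1's own list the top peak, at 9.83, lay at chromosome 3, 101391701 to 101400585, inside Igsf3, the gene of an immunoglobulin-domain membrane protein. Fold enrichment, p and q of a peak are the authors' own values and were used only to describe, rank or filter peaks within a list. Replicate 1 had 217311 peaks over 88.0 Mb and replicate 2 had 195123 peaks over 83.5 Mb, a mean of 206217 ± 15689 peaks (SD, n = 2). Peaks were narrow, with a median width of 287 ± 12.7 bp (SD, n = 2). The pooled list had 239382 peaks over 130.1 Mb. The replicated list had 120755 peaks over 97.8 Mb, 3.69% of the genome without assembly gaps, with a median width of 600 bp.

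Most peaks of each replicate touched a peak of the other, though fewer overlapped it closely. Of replicate 1's peaks, 60.6% shared at least 1 base with a peak of replicate 2, against 6.23% for circularly shifted lists. Of replicate 2's peaks, 66.3% were shared with replicate 1, against 6.82% for shifted lists. Both shares were 9.72 to 9.73 times the chance level (one-sided permutation test over 100 shifts, p = 0.0099, the smallest these permutations can give). When the overlap had to cover at least as much of each peak as it left out, 32.9% of replicate 1's and 36.6% of replicate 2's peaks were shared, against 1.42% and 1.58% by chance. Sharing of at least 1 base rose with fold enrichment from 36.7% in the lowest to 97.6% in the highest decile of replicate 1. In replicate 2 it fell from 49.3% in the lowest decile to 44.3% in the next and then rose to 98.2% in the highest. Peaks of the highest decile were also wider, with medians of 841 and 855 bp against 205 and 228 bp in the lowest, and no chance level was computed by decile. The bases in both replicates' peaks made up 42.7% of the bases in either. All 120755 replicated peaks were pooled peaks with the same start and end, and 86.7% of them overlapped peaks of both replicates. The replicated list kept 50.4% of the pooled peaks, from 8.19% of the lowest decile by fold enrichment to 99.97% of the highest.

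**Figure D1:**
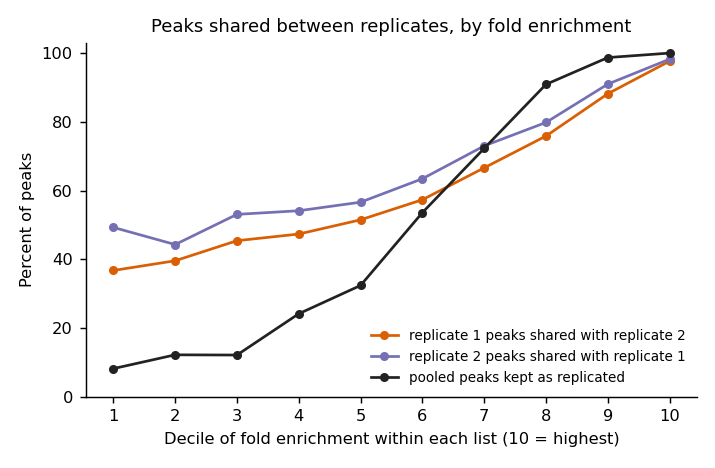
Percent of peaks (vertical axis) shared with the other replicate, or kept by the authors as replicated, by decile of the authors' fold enrichment within each list (horizontal axis, 10 is the highest); each point is 1 decile of 1 list. All 3 lines end above 97% in the highest decile, and the pooled list starts at 8.19%.

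Promoters and introns held most of the marked regions. The middle of 20.7% of replicated peaks lay within 1 kb of a transcription start site, 3.24 times the share of shifted peaks. Introns held 49.1%, 1.21 times chance, exons 4.79%, 1.40 times chance, and the space between genes 25.5%, or 0.512 times chance. Each of the 4 places differed from chance (one-sided permutation test over 100 shifts, p = 0.0099 each, the smallest they can give). In the replicates' own lists promoters held 18.1% ± 0.182, exons 4.86% ± 0.103, introns 50.6% ± 0.262 and the space between genes 26.4% ± 0.341 of peaks (SD, n = 2). The excess in exons depended on taking the middle of the peak: with any overlap counted, exons fell to 0.983 times chance (one-sided permutation p = 0.277).

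The mark flanked start sites and often left the start site itself bare. Of 21938 protein-coding start sites, 18.4% were covered by a replicated peak, while 27.0% were covered 500 bp upstream and 36.5% were covered 1000 bp downstream. Start sites of housekeeping genes were bare in 21 of the 25 genes with a peak 500 bp to 3 kb away, or 84.0%, close to the 73.6% of all protein-coding genes with such a peak. Lists of facial genes, and also lists of other tissues, went the other way. Only 13 of 38 facial mesenchyme regulators with a marked flank had a bare start site (34.2%), as did 3 of 20 surface epithelium genes (15%), 4 of 15 endothelial genes (26.7%), 5 of 18 forebrain neuron genes (27.8%) and 13 of 28 facial signalling genes (46.4%). The lists of genes known from heart, with 5 of 13 (38.5%), and of Hox genes, with 17 of 34 (50%), also fell below the share of all genes. Blood and immune genes, with 8 of 10 bare (80.0%), skeletal muscle genes, with 8 of 13 (61.5%), and cartilage and bone genes, with 10 of 17 (58.8%), stood nearer to it. In the crest glia and melanocyte list 5 of 10 were bare (50%), in the liver list 3 of 5 and in the germ cell list 3 of 5 (60% each), and the tooth matrix list had 1 gene with a marked flank. Over the replicates' own peaks 15.03% ± 2.24 of start sites were covered, against 22.2% ± 0.870 at the highest point upstream and 31.04% ± 0.496 at the highest point downstream (SD, n = 2), so the dip was larger than the spread between replicates. The shares of the lists are descriptions, since genes are not replicates.

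**Figure D2:**
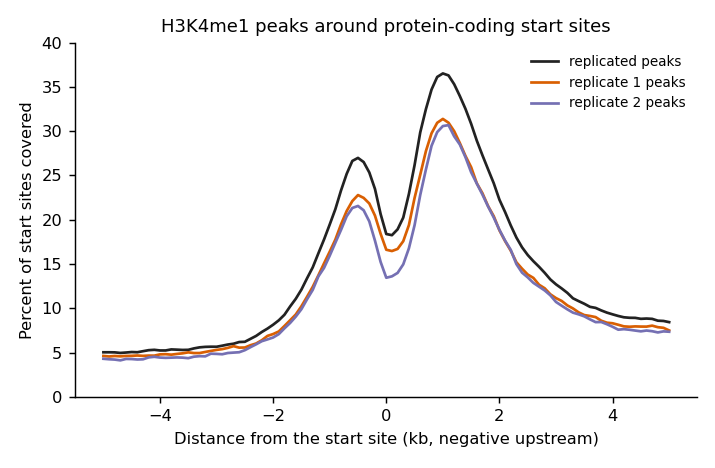
Percent of the 21938 protein-coding start sites covered by a peak (vertical axis) at each distance from the start site in kb (horizontal axis, negative upstream, steps of 100 bp); the lines are the replicated list and each replicate's own list. The replicated list covers 18.4% of start sites and 36.5% of positions 1000 bp downstream.

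Facial mesenchyme regulators and facial signalling genes stood in more H3K4me1 than other genes. Among facial mesenchyme regulators, the transcription factors known from facial neural crest, a median of 12.8% of the bases within 50 kb of the start site lay in replicated peaks (10.9% ± 1.05 over the replicates' own peaks, SD, n = 2), where matched random lists had a median of 2.87%. Of its 41 members, 27 lay above the upper quartile of all protein-coding genes, 10.8%, and Tbx22 was the 1 member with no replicated peak. The homeobox gene Prrx2 had 46.4% (41.3% ± 2.85, SD, n = 2) around its start site at chromosome 2, 30834972, Alx4 had 38.6% and Snai1, a regulator of cell migration from epithelia, had 33.4%. The median over all 21938 protein-coding genes was 4.30%, and 19.9% of them had no replicated peak in the window. The facial mesenchyme median lay at percentile 100 of 10000 random lists matched on gene density, which describes these libraries and is no test across genes.

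Facial signalling genes came next, with a median of 12.504% (10.8% ± 0.887, SD, n = 2) at percentile 100 and 19 of 30 members above the upper quartile. Notch1, a receptor, had 46.7% (41.2% ± 0.561, SD, n = 2) around its start site at chromosome 2, 26516663. The ligand Wnt11 had 38.9% and Gli2, an effector of hedgehog signalling, 36.6%, while the growth factor Fgf10 had 1.25%. Surface epithelium genes had a median of 9.70% (8.71% ± 0.715, SD, n = 2) at percentile 99.6. Grhl3 had 25.4%, Jup (plakoglobin) 24.2% and Irf6 18.9%, while Trp63, a regulator of stratified epithelia, had 0.895%. Cartilage and bone genes had a median of 7.49% (6.80% ± 0.643, SD, n = 2) at percentile 99.2, with type I collagen gene Col1a1 at 30.5%, Comp at 27.0%, Alpl (alkaline phosphatase) at 23.1% and the X-linked Phex at 0%. With random lists matched also on the GC content of the windows, a choice made after seeing the data, the surface epithelium list fell to percentile 70.2, while the cartilage and bone list stood at 99.6, facial mesenchyme at 100, facial signalling at 99.97 and housekeeping at 97.5. Cartilage and bone genes fell below percentile 95 with windows of 20 kb (78.7) and 100 kb (90.2) either side, and with unmatched random lists (93.4).

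The lists for other cell types and tissues ranged widely, and housekeeping and forebrain neuron genes also lay above the 95th percentile. Skeletal muscle genes had a median of 5.33% (percentile 83.4), with Tnnt3 at 46.4% beside the highly marked Mrpl23 and the large sarcomere gene Ttn at 0%. Endothelial genes had 5.21% (percentile 78.1), led by Eng with 31.03%, and Tek had 1.03%. Blood and immune genes had 8.33% (percentile 80.2), with Runx3 at 25.5% and the macrophage gene Lyz2 at 0%. Crest glia and melanocyte genes had 3.30% (percentile 50.3), with the nerve growth factor receptor gene Ngfr at 42.6% and the pigment gene Tyr at 0%. Of the tissues elsewhere in the embryo, heart genes had 6.39% (percentile 93.6), liver genes 2.69% (percentile 11.0) and germ cell genes 3.15% (percentile 29.5), in which Prm1, Tnp2 and Prm3 share most of a window. Forebrain neuron genes had 6.24% (percentile 95.5), led by Bcl11b, a zinc-finger gene known also from skin and teeth, with 43.9%, and Slc17a6 had 0.779%. The forebrain list fell below 95 with windows of 100 kb (88.2), numbers of peaks (72.5), unmatched lists (82.1), no start-site bases (85.1) and replicate 1's own peaks (93.1). It stayed above with windows of 20 kb (99.8), q of at most 0.01 (95.6), peaks above the median fold enrichment (99.5) and replicate 2's own peaks (95.9). Tooth matrix genes had the lowest median, 0.775% (percentile 3.59), and 5 of 11 had no peak, although Sp6 had 26.1%. The tooth list rose above percentile 5 with windows of 100 kb (8.3), numbers of peaks (8.8) and no start-site bases (16.4). It stayed below 5 in the other settings fixed beforehand. Hox genes, which share windows within their clusters, had 12.01% (percentile 70.1), from 20.9% at Hoxd8 to 3.04% at Hoxb13. Housekeeping genes had 11.2% (percentile 98.2), with the ribosomal Rplp0 at 34.8% and the X-linked Hprt at 0%. The housekeeping list fell to percentile 91.8 with windows of 100 kb. Matching also on window GC took the heart list to percentile 3.46, the Hox list to 1.00 and the liver list to 1.02, below the 5th percentile, took the forebrain list to 92.6, and took the tooth list to 14.4. Without bases within 2.5 kb of start sites the heart list stood at 98.4 and the endothelium list at 95.5, its highest. The heart list also passed 95 with peaks above the median fold enrichment (95.3) and in replicate 1's own peaks (96.1). In the other settings it stood below 95, with 94.8 in replicate 2's own peaks.

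**Figure D3:**
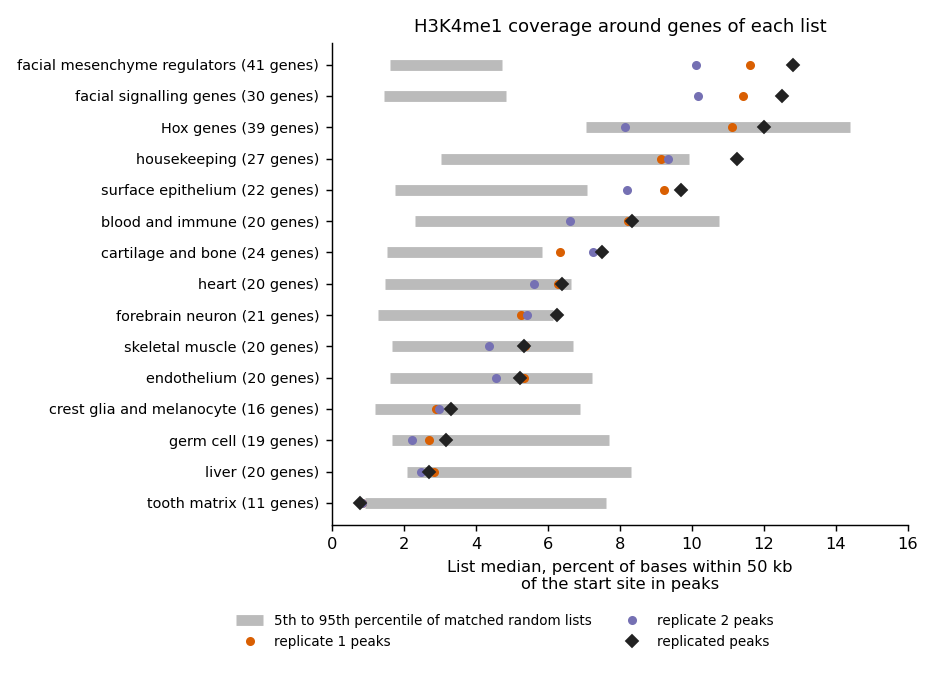
Median percent of the bases within 50 kb of the start site that lie in peaks (horizontal axis) for each of the 15 gene lists (vertical axis); diamonds are the replicated list, circles each replicate's own list, and grey bars the 5th to 95th percentile of 10000 random lists matched on gene density. Facial mesenchyme regulators (12.8%) and facial signalling genes (12.504%) lie to the right of their bars, and tooth matrix genes (0.775%) to the left.

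Of all protein-coding genes G430095P16Rik, at chromosome 8, 84723007, had the highest share, 68.6% of its window in replicated peaks (58.1% ± 0.668 over the replicates' own peaks, SD, n = 2). Rxra, a retinoid X receptor, had 57.4% (49.4% ± 0.563), Ncor2, a nuclear receptor co-repressor, 57.4% (53.2% ± 2.14), and Ski, a repressor of TGF-beta signalling, 57.2% (51.2% ± 1.39; SD, n = 2 each). The retinoic acid receptor gene Rara had 50.5% (47.3% ± 0.677, SD, n = 2) and the nuclear lamin gene Lmna 50.8% (44.1% ± 0.692, SD, n = 2). The other genes chosen by the same rule were Dohh, Gse1, Flrt1, Mrpl23, Nxn, Ifrd2, Synpo, Cbarp, Igsf3, Bahcc1, Dusp7, Ahdc1, Asb6 and Pmepa1, from 56.4% at Dohh down to 48.1% at Pmepa1. Asb6, with 48.3%, starts next to Prrx2 and shares its window.

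Peaks within 3 kb of each other formed 56522 domains, 29308 of them of 1 peak, and 515 spanned 20 kb or more and held 10.4% of the bases in peaks. The domain with most bases in peaks lay at chromosome 8, 84698042 to 84816231, with 48 peaks over 90.3 kb (78.3 kb ± 0.226 in the replicates' own peaks, SD, n = 2), and the start site nearest to its middle was that of G430095P16Rik. The next lay at chromosome 4, 155113581 to 155224165, over the start site of Ski, with 87.8 kb in 46 peaks (77.5 kb ± 1.29, SD, n = 2). Ssbp3, a co-factor of LIM-homeodomain factors, followed with 75.2 kb at chromosome 4, 106906998 to 107006406. A domain with 71.9 kb in peaks lay over the start site of Rxra at chromosome 2, 27666121 to 27751620, and one with 49.6 kb in peaks lay over that of Bcl11b at chromosome 12, 107947318 to 108006888. The start sites nearest to the middle of the remaining domains of the top 15 were those of Gins2, Tgoln1, Gse1, Ncor2, Shb, Zmiz1, Capzb, Neurl1a, Mbnl2 and Glod4. For some of these the middle lay outside the gene: Gins2 (63.8 kb from the start site), Tgoln1 (73.6 kb), Neurl1a (134 kb) and Glod4 (70.7 kb). The middle of the leading domain also lay outside G430095P16Rik, 34.1 kb from its start site. The rule takes the nearest start site only, so these domains may lie in the body of another gene, which was not determined. Which genes were nearest to the leading domains depended on the settings. Nfix, Tcf7l1, Sh3pxd2a and Nxn, none of them among the 15 named above, were nearest to leading domains under other settings. Joining peaks within 1 kb kept 7 of the 15 genes among the top 15, the longer distance 3 and distal peaks only 6. Without replicate 1 there were 11 of the 15, and without replicate 2 there were 8. These counts compare gene names. A domain whose middle shifts can take another name, so they do not measure whether the same domains led. G430095P16Rik was not the gene nearest to a top 15 domain in either replicate's own list.

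Binding-site words of several transcription factor families were denser in peaks away from start sites than in windows of the same width, chromosome and GC content outside any peak. The palindrome of nuclear factor I (NFI) was 4.09 ± 0.693 times as dense (SE over chromosomes), from 176 hits in peaks and 43 in windows, and the MEF2 word was 2.24 ± 0.0884 times as dense. The homeodomain word TAATTA had a ratio of 1.38 ± 0.0197, the TEAD word 1.37 ± 0.0162, the E-box CAGCTG 1.33 ± 0.0132, the TFAP2 word 1.27 ± 0.0133, the FOX word 1.22 ± 0.0161 and the AP-1 word 1.19 ± 0.0190 (SE over chromosomes). The E-box CAGATG, known as a Twist site, stood at 1.11 ± 0.00750 and the RUNX word at 1.13 ± 0.0147. The SP/KLF word, at 1.58 ± 0.0427, the CTCF word, at 1.53 ± 0.102, and the RFX word, at 1.31 ± 0.0683, were also denser. Compared with the same letters shuffled, SP/KLF fell to 1.16 and TFAP2 to 1.14, still above 1. CTCF (1.64) and RFX (1.71) rose, and the homeodomain word stood at 1.36. Windows were not matched on CpG content. Of the 22 words, 15 were denser and 2 sparser in peaks by a 95% interval from a jackknife over chromosomes. The sparser words were those of SOX factors, at 0.882 ± 0.0150, and of PITX, at 0.921 ± 0.0112, and for PITX the direction turned to 1.04 when compared with the same letters shuffled. The POU word (1.11) and the TCF/LEF word (1.08) were also denser, but POU was not told from 1 in the middle 500 bases of peaks (1.07), nor was TCF/LEF against shuffled letters (1.01). The words of ETS (1.10), HNF4 (1.04), SRF (1.02), GLI (0.988) and GATA (0.967) were not told from 1 in the replicated list. The ETS word was denser in both replicates' own peaks (1.16 and 1.29) but sparser against shuffled letters (0.887), and the HNF4 word was denser against shuffled letters (1.23). In the replicates' own distal peaks the ratios were 4.91 ± 0.220 for NFI, 2.36 ± 0.00409 for MEF2 and 1.40 ± 0.0498 for the homeodomain word (SD, n = 2). For NFI and MEF2 these SDs understate the error. The SE over chromosomes was 0.849 in replicate 1 and 0.996 in replicate 2 for NFI, and 0.130 and 0.126 for MEF2. All replicated peaks together, those at promoters included, were GC-rich, with 50.6% against 42.1%, and had a CpG observed over expected of 0.292 against 0.195. These values were set against windows of the same width and chromosome that were not matched on GC and could overlap peaks. Without the match on GC the homeodomain word fell to 0.540, and the MEF2 word, at 0.934 (95% interval 0.842 to 1.03), was not told from 1.

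**Figure D4:**
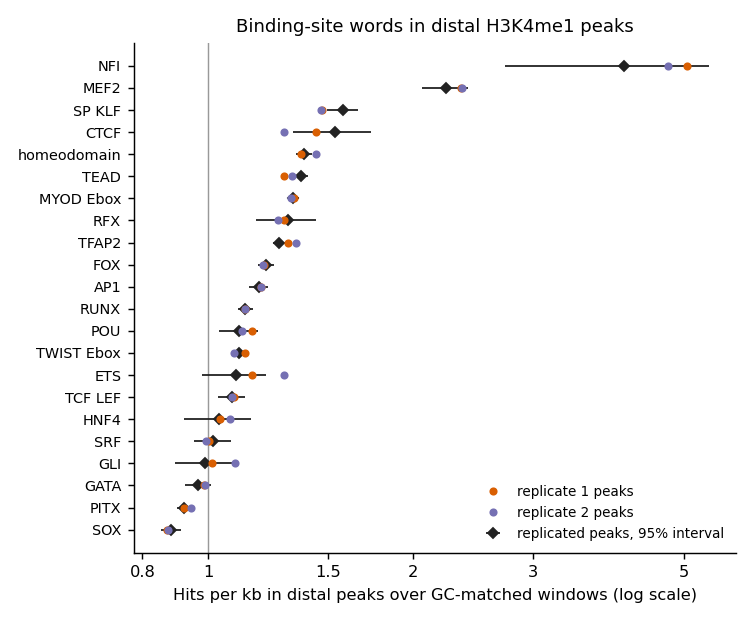
Density of each of the 22 words in distal peaks over that in GC-matched windows (horizontal axis, log scale, 1 is equal density); diamonds are the replicated list with the 95% interval from the jackknife over chromosomes, circles each replicate's own list. NFI (4.09) and MEF2 (2.24) lie farthest above 1 and SOX (0.882) farthest below.

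Chromosomes 11 and 19 were the most covered, and X stood far below every autosome. Replicated peaks covered 6.83% of chromosome 11 and 5.196% of chromosome 19, and 2.68% of chromosome 3, the lowest autosome. The median over the autosomes was 4.27%. On X they covered 0.189%, 22.6 times less than that median, in 521 peaks, and there was no peak on Y. In the replicates' own lists X had 0.197% ± 0.0212 and the median autosome 3.75% ± 0.184 (SD, n = 2), so the gap was larger than the spread between replicates. Tbx22, Phex and Hprt, all on X, had no replicated peak within 50 kb of their start sites, while the X-linked facial signalling gene Efnb1, named after its values were seen, had 8.18% of its window in peaks.

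**Figure D5:**
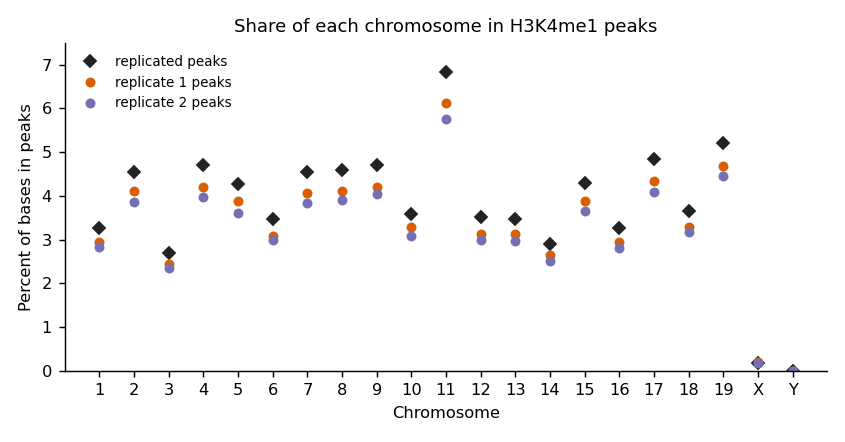
Percent of each chromosome's bases, without assembly gaps, in peaks (vertical axis) by chromosome (horizontal axis); diamonds are the replicated list and circles each replicate's own list. Autosomes lie between 2.68% and 6.83% in the replicated list, and X at 0.189%.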

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

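No paired analysis was possible because there is a single group. Of the values that answer a comparison, 80 were counted as staying, 28 as moving and 1 as reversing. For replicate overlap and genomic location, staying meant the same direction against chance, and sizes could change. Promoters counted as staying at 2.42 times chance with windows of 2.5 kb, against 3.24 (SD of the replicates' own folds 0.0263, n = 2). Overlap counted as staying under the strictest rule, with 32.9% of replicate 1's peaks shared against 60.6%. For the other comparisons staying meant within the spread between replicates, or within 1.5 times for counts. Of the values of single lists, genes and words, 242 stayed, 201 moved, 6 reversed in direction, 8 density ratios of words came past the interval and 2 fell inside it (TCF/LEF at 1.01 against shuffled letters and POU at 1.07 in the middle 500 bases). The 8 were ETS at 0.887 and HNF4 at 1.23 against shuffled letters, ETS at 1.16 to 1.29 without replicate 1 or 2, and, without the match on GC, ETS (2.63), GLI (2.09), SRF (0.835) and GATA (0.753). Density ratios counted as staying kept their direction, or an interval that includes 1, and could change in size. The SP/KLF ratio, for example, went from 1.58 to 4.55 without the match on GC. Matching random lists also on window GC and leaving out genes on X and Y were chosen after seeing the data. The cause was not tested for any value below unless it is given.

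With peaks above the median fold enrichment, by construction fewer, there were 102002 peaks per replicate, 83.5% of pooled peaks were replicated, and 14.3% of start sites were covered, with 19.5% at the highest point upstream and 30.4% downstream. X then had 0.0779% of its bases in peaks and the median autosome 2.85%, GC was 51.1% and CpG observed over expected was 0.307. With q of at most 0.01 the share of replicated peaks was 56.5%. Counting any overlap turned the excess in exons to 0.983 times chance (one-sided permutation p = 0.277). Start sites over 10 kb from any other were covered in 25.1% at the highest point upstream and 31.1% downstream.

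Without replicate 1 or without replicate 2, that is with the other replicate's own peaks in place of the replicated list, start sites were covered in 13.4% to 16.6%, with 21.6% to 22.8% upstream and 30.7% to 31.4% downstream. X had 0.182% to 0.212% and the median autosome 3.62% to 3.88%, GC was 50.6% to 51.1%, and CpG observed over expected was 0.283 to 0.289.

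The number of gene lists above the 95th percentile was 6, and 3 with windows of 100 kb. The number below the 5th percentile was 1, and 0 with windows of 100 kb, 0 with the number of peaks and 3 when matched on gene density and window GC. These are numbers of lists and do not show which list it was. Without bases within 2.5 kb of start sites it was the liver list (percentile 2.29) in place of the tooth list (16.4). Joining over the longer distance gave 28779 domains. Without the match on GC, 8 words were sparser, and the homeodomain (0.540), FOX (0.675), TCF/LEF (0.801) and POU (0.571) words reversed. MEF2 also went below 1, to 0.934, but with an interval that includes 1. These words are rich in A and T and the replicated peaks as a whole are GC-rich, so unmatched windows may hold more of them for that reason. The GC content of distal peaks alone was not measured. Against shuffled letters PITX reversed to 1.04. Depth is unknown, so peaks missed for want of reads cannot be told from regions without the mark.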

Other observations

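The patterns below were seen in these data, and each was then tested on the same data, so the explanations are hypotheses; the tests were chosen only after the patterns were seen, with their bounds set before the tests' own values. With 1 group, no biological explanation was tested for the X chromosome or for the start sites.

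On X, 662 of 948 protein-coding genes had no replicated peak within 50 kb of the start site (69.8%), against 16.9% of autosomal genes. The most covered X genes, named after their values were seen, included Bcor, a co-repressor gene, with 17.0% (13.4% ± 0.903 over the replicates' own peaks, SD, n = 2), and the ephrin gene Efnb1, with 8.18%.

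X windows of 100 kb had fewer coding start sites, lower GC (a median of 38.9% against 41.4%) and more masked repeats (45.7% against 31.7%) than autosomal windows. Autosomal windows matched on all of these held 1.01% of bases in replicated peaks and X windows 0.199%, a ratio of 5.07, and at least 4.16 for every single autosome. Composition may therefore account for part of the 22.6-fold gap, and the tests argue against it as the whole. A lower copy number of X against a fixed threshold cannot be told apart from other causes. Bringing matched autosomal windows down to the X level needed a bar of 1.74 and 1.82 times the 5th percentile of fold enrichment in the replicates, but of 2.80 and 3.01 times in −log10 p, and the labels do not give the sex ratio of the pools. The bound set beforehand counted copy number as possible if either measure met it in either replicate. Fold enrichment met that bound and −log10 p did not, which leaves other causes open. That bound was sized for a pool of males only, while these pools held both sexes, where the mean loss of X copies is smaller. Meeting it therefore says little for copy number.

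Start sites of facial mesenchyme regulators with a marked flank were bare in 34.2%. Random lists matched on CpG and GC content of the start sites had a mean of 71.7% (5th to 95th percentile 60.5% to 81.6%), so CpG and GC content, at percentile 0, did not account for it. Nor did wide H3K4me1 coverage around the gene (mean of matched lists 70.6%, percentile 0). An annotated start site away from the one used was tested on genes whose transcripts all start within 1 kb: 6 of 22 were bare (27.3%), against a mean of 68.8% (percentile 0), while for facial signalling genes, with 7 of 13 bare (53.8%, against a mean of 69.3%), the share was within the range of random lists (46.2% to 92.3%, percentile 12.6). Under CpG and GC matching the share was also low in facial signalling (percentile 0.14), surface epithelium (0), endothelium (0.115), forebrain (0.02) and Hox genes (0.205), but not in heart (7.37, though 0.7 when matched on coverage), crest glia and melanocyte (13.1), cartilage and bone (61.5), housekeeping (75.8), skeletal muscle (78) or blood and immune genes (90.8).

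Among arrangements of the E-box CAGATG and TAAT with 0 to 15 bases between them, TAATNNNNNNCAGATG was the densest over matched windows in the replicated list and in both replicates' own peaks. It had 387 hits in peaks and 110 in windows, a ratio of 3.52 ± 0.424 (SE over chromosomes), 2.54 times the median spacing. Over the replicates' own peaks the ratio was 4.997 ± 0.0651 (SD, n = 2), from 70 hits in windows for replicate 1 and 61 for replicate 2. That SD understates the error, as the SE over chromosomes was 0.615 in replicate 1 and 0.753 in replicate 2. A joint element bound by E-box and homeodomain factors may explain the top spacing. The control E-box had its top at the same spacing, CAGCTGNNNNNNATTA, with a ratio of 3.87 ± 0.457, higher than that of CAGATG in the replicated list. Over the replicates' own peaks it was 3.03 ± 0.218 (SD, n = 2). It stood at 2.33 times its own median spacing in the replicated list, and at 1.95 and 1.72 times in the replicates' own lists, where CAGATG stood at 3.75 and 3.70 times. The control had 357 hits in replicate 1's peaks and 341 in replicate 2's, more than the 353 and 302 of CAGATG. Its lower ratios there came with more hits in windows, 124 and 107, from a single draw of windows per list. Distal peaks with the element, in which either E-box was counted, were no more often near facial regulators than draws of distal peaks matched on width. Of 801, 15 (1.87%) lay within 200 kb of a facial mesenchyme or signalling gene, against a mean draw of 2.79%, a ratio of 0.671. The ratio was also below 1 for surface epithelium (0.427), forebrain (0.629), liver or germ cell (0.780) and housekeeping genes (0.185). As every list fell below 1 and draws were matched on width only, 1 may not be the level without preference. The test therefore cannot decide whether the element favours facial genes.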
